A study of Danio rerio with 107 samples.

How the data were processed

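Per the labels, zebrafish embryos without their chorion were held at 28 °C from 6 to 48 hours after fertilisation in water with a chemical at its own EC80 or with DMSO alone (at most 0.64%), and the RNA of 8 embryos was pooled for each array. The authors labelled 0.5 µg of RNA with Cy3 and hybridised it to one-colour Agilent arrays whose probes follow the Zv9 (danRer7) transcripts. Per the labels 116 arrays were run, 4 planned per treatment, and the authors removed 9 as outliers, leaving 107. Groups with under 4 would have lost these 9.

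The scanner files hold intensity values that, per the file headers, were made with Agilent Feature Extraction 11.5.1.1 by subtracting the background and detrending within each array, with no normalization between arrays. The deposited series table holds log2 values that the authors normalized between arrays with limma by an unstated method; it covers 56673 probes, and the medians of its columns lie between 8.36 and 8.40. The intensity values were used for every comparison, and the deposited log2 values only as an alternative.

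Spots of 1 probe were averaged, which gave 60022 probes, and gene names were updated from the supplied annotation. A gene with several probes was represented by the probe with the highest mean over all arrays, and a probe without a gene name was its own feature, for 42787 features. A feature was kept if it was well above background on at least 3 arrays of at least 1 group (both arrays for triiodothyronine). This left out 1111 features, and 36 more were missing on 10 or more arrays, so 41640 were tested, 20765 of them with a gene name. The log2 of the processed signal minus the 75th percentile of the array gave the normalized log2 signal. No spot was saturated, and 10 to 236 spots per array were flagged by Feature Extraction as non-uniform or as outliers of their probe and left out. Coordinates are on Zv9. Cross-hybridisation between paralogs was not tested.

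All arrays entered a single fit of 29 groups in limma 3.58.1 (R 4.3.3, version 1.17.8 of data.table, figures with python 3.11.15), with 78 residual degrees of freedom and 2.69 prior degrees of freedom. Each chemical was set against the DMSO arrays of its batch with the two-sided moderated test, and p was adjusted by Benjamini-Hochberg per chemical. The spread for triiodothyronine, with 2 arrays, is pooled over all groups. Pairs of related chemicals were compared as the difference of their differences from DMSO, and the DMSO batches with a moderated F test. Class similarity was the mean correlation of fold changes across genes in pairs from different batches, tested by 100000 permutations of the class names within batches. CP-634384 had no class.

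Of 474 members of 31 gene lists, 458 were measured. Lists were tested with camera at the preset correlation of 0.01 and with an estimated correlation, adjusted over all 775 tests. The comparisons, classes, pairs, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the named genes are the first of the 10 largest rises and falls past the threshold with every array of the chemical on one side of the DMSO mean and a symbol that is not a clone or locus name, and the members of a list with the smallest adjusted p. Members of the estrogen, androgen and thyroid lists are named for chemicals of their class whether or not they passed. For pairs they are the 10 genes with the smallest p and the genes named for either chemical. The 6 immediate early genes as a set, ddb2, si:ch211-103n10.5, and fkbp5, cry1a and per1b in diisobutyl phthalate were chosen after their values were seen. Where all arrays of 1 side were not well above background, a fold is given as "at least", with the dim arrays set to no lower than the lowest signal well above background on the same array.

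Simulated data had the arrays' spread and 50 changed genes per size. At a log2 change of 1 the fit called 56% for Ziram, 68% for Butylparaben and 38% for triiodothyronine, and at 2, 84%, 92% and 72%. There were 4, 11 and 4 false calls and 0 in an unchanged chemical. Real arrays may give more, as another raloxifene split called 3123.

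The alternatives were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, slide as a block, replicate number as a block, all 14 DMSO arrays as 1 control group, the authors' deposited values, and leaving out each array in turn. Class similarity was also computed with Spearman correlation and over called genes alone.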

Results

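The series measured RNA in pools of whole zebrafish embryos that had been held from 6 to 48 hours after fertilisation in water with DMSO alone or with 1 of 25 chemicals. Per the labels each chemical was given at its own EC80, so the doses were not matched between chemicals. Each of the 107 arrays held the RNA of 1 pool of 8 embryos. The labels place the arrays in 29 groups and 4 exposure batches. DMSO was present in every batch, with 3, 3, 4 and 4 arrays in batches 1 to 4. Most chemicals had 4 arrays. Abamectin, CP-634384, Haloperidol, Kepone and raloxifene (Raloxifene_hydrochloride) had 3, and triiodothyronine (353_Triiodothyronine) had 2. The 75th percentile of the processed signal ranged from 343.6 to 1152 between arrays, and 90.5% to 97.9% of the spots of an array were well above background. The number of arrays limits the precision: the median residual standard deviation of a feature was 0.30 on the log2 scale.

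The comparisons asked which genes each chemical changed relative to the DMSO arrays of its own batch. They also asked whether structurally related chemicals differed, and whether chemicals of one hormone receptor class resembled each other. A feature below is a named gene or a probe without a gene name, and the largest rises and falls are ranked among genes whose symbol is not a clone or locus name. "Rose" and "fell" mean an adjusted p under 0.05 in limma's moderated test over 41640 features. Counts over the list alone adjust p over the genes of that list. Changes are log2 values against DMSO, ± the standard error. For each gene taken from the ranked rises and falls, every array of the chemical lay on the same side of the mean of its DMSO arrays. A call is described as unstable where it was lost without at least 1 array or under another background correction, normalization, filter or block, or with the deposited values; pooling the DMSO arrays of all batches is treated apart. The arrays lay on 16 slides, each with several groups, so each count is followed by the count with slide as a block.

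**Figure D1:**
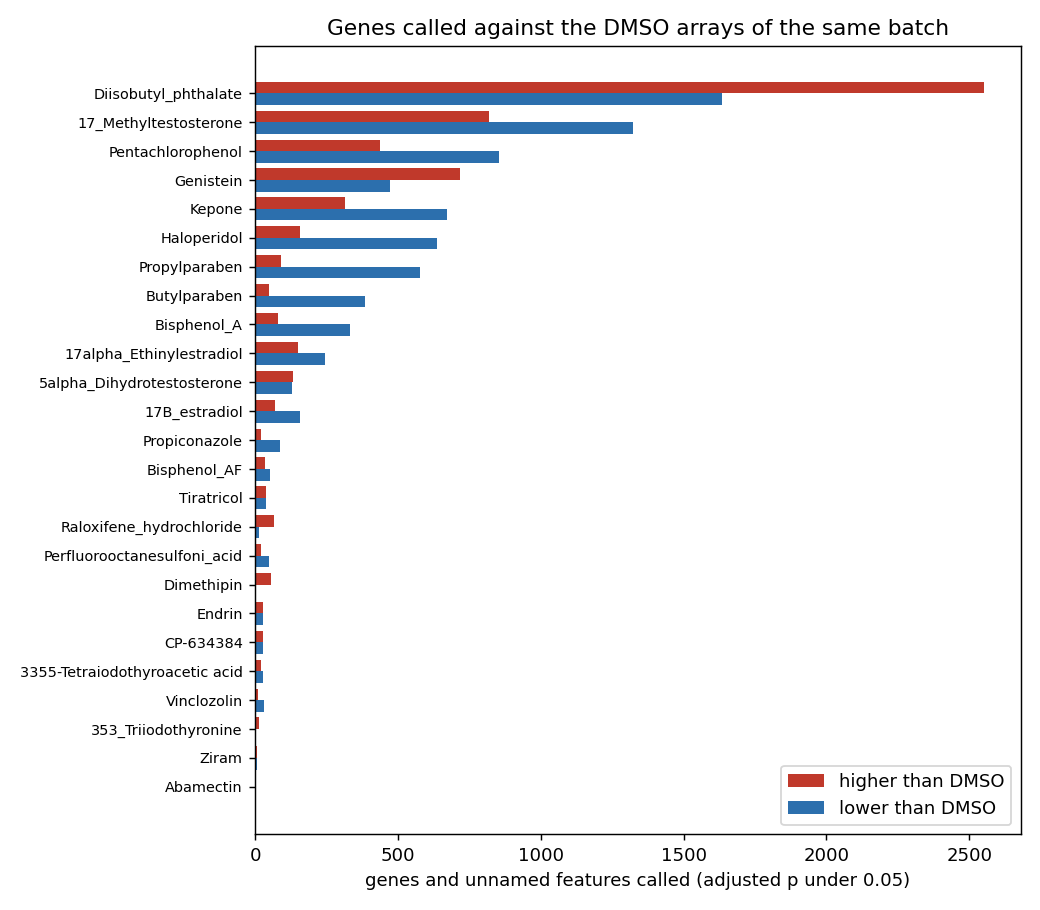
Bars give the number of features called higher (red) and lower (blue) than the DMSO arrays of the same batch, on a linear axis that starts at 0, for each chemical under its label. Diisobutyl_phthalate stands at the top with 2552 higher and 1635 lower, and Abamectin at the bottom with 2 lower.

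The DMSO arrays themselves differed between batches. The F test over the 4 batches called 826 features, and 501 with slide as a block. Batches 2 and 4 differed in 2532 features and batches 2 and 3 in 0, where limma gave 1954 features an unadjusted p under 0.05. A set of 6 immediate early and stress-induced genes (fosab, nfkbiaa, socs3a, sik1, tcima and arrdc3b), put together after their values were seen, averaged -0.12 ± 0.23 (SD, n = 3) in DMSO batch 1. It averaged -1.53 ± 0.02 (SD, n = 3) in batch 2, -1.21 ± 0.10 (SD, n = 4) in batch 3 and -1.61 ± 0.22 (SD, n = 4) in batch 4. Falls of these genes in batch 1 chemicals and rises in the other batches stand against these levels. Pooling all 14 DMSO arrays ended the calls of nfkbiaa in estradiol, bisphenol A, Propiconazole, Raloxifene, Tiratricol and Ziram, of socs3a in estradiol, of arrdc3b in Ziram and of tcima in bisphenol AF, Ziram and Abamectin.

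The thyroid hormone receptor ligands shared a small set of strongly changed genes. Tiratricol (triiodothyroacetic acid) raised the globin genes hbba2 by 6.56 ± 0.39 (94.5-fold, adjusted p = 5.48e-24) and hbz by 5.05 ± 0.27 (33.0-fold, adjusted p = 4.07e-26). It also raised opn1lw2, a red cone opsin (2.31 ± 0.37), the transcription factor nfil3-6 (1.63 ± 0.25), dio3a, a deiodinase that inactivates thyroid hormone (1.26 ± 0.18), and the thyroid receptor gene thrb (1.04 ± 0.19). Its largest falls were gch2, a pteridine pigment enzyme (-2.20 ± 0.18), fosab (-2.13 ± 0.28), arrdc3b (-1.62 ± 0.21) and akr1b1.1 (-1.62 ± 0.19), with nfkbiaa at -1.32 ± 0.14 and tmem130 at -1.43 ± 0.19. On Zv9 hbba2 (named zgc:92880 in the files) lies on chromosome 3 at 55942902 to 55943723, hbz on chromosome 12 at 21694944 to 21706034 and gch2 on chromosome 12 at 26612194 to 26618916. In the thyroid axis list 2 of 17 measured genes rose (2 over the list alone, camera adjusted p = 0.00439, and 0.0457 with an estimated correlation), a call lost with slide as a block (adjusted p = 0.0683) and with the deposited values (0.066). In the pigment cell list 1 of 14 genes fell, and 6 over the list alone (camera adjusted p = 5.63e-11). Tiratricol called 76 features with 4 arrays against 3, 38 higher and 38 lower, and 92 with slide as a block. The thrb call is unstable, and the fosab call was lost with pooled DMSO arrays.

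Tetraiodothyroacetic acid raised hbba2 by 3.59 ± 0.39 (adjusted p = 1.76e-10), hbz by 2.77 ± 0.27, nfil3-6 by 2.07 ± 0.25, opn1lw2 by 1.92 ± 0.37 and dio3a by 1.72 ± 0.18. The genes gch2 (-2.18 ± 0.18), tmem130 (-1.60 ± 0.19) and akr1b1.1 (-1.55 ± 0.19) fell. In the pigment cell list 3 of 14 genes fell, and 8 over the list alone (camera adjusted p = 4.86e-13). They included the melanin genes tyrp1a (-0.91 ± 0.18) and slc24a5 (-0.70 ± 0.14). The fit called 48 features with 4 arrays against 3, 20 higher and 28 lower, and 60 with slide as a block. The calls of opn1lw2, tyrp1a and slc24a5 are unstable.

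Triiodothyronine, with 2 arrays against 3, raised 14 features and lowered 0. At an unadjusted p under 0.05 it had 1074 features, and limma with slide as a block called 24, 19 higher and 5 lower, and with the deposited values 60 higher and 11 lower. The rises included hbba2 (3.33 ± 0.46, adjusted p = 4.02e-06), hbz (2.86 ± 0.33), nfil3-6 (1.89 ± 0.29), b2m (1.24 ± 0.21), the retinoic acid hydroxylase cyp26a1 (1.02 ± 0.22) and the glutathione synthesis gene gclm (0.92 ± 0.18). Of these only hbz kept its call without each array in turn, and without 1 array the count was 5 to 12. The values of dio3a (0.97 ± 0.22, adjusted p = 0.0575) and gch2 (-0.88 ± 0.22, adjusted p = 0.201) did not pass; both passed with slide as a block, with pooled DMSO arrays and with the deposited values, and dio3a also with quantile normalization.

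CP-634384, a compound known here by its code, raised hbba2 (3.25 ± 0.41, 9.48-fold, adjusted p = 8.3e-08), hbz (3.16 ± 0.29), dio3a (2.04 ± 0.19), nfil3-6 (1.91 ± 0.26), b2m (1.43 ± 0.19) and thrb (0.93 ± 0.20). It lowered gch2 (-2.14 ± 0.20), gngt2b, a cone transducin subunit (-1.89 ± 0.35), tmem130 (-1.66 ± 0.21) and xdh, xanthine dehydrogenase (-1.01 ± 0.20). The pigment cell list (2 of 14 fell, 4 over the list alone, camera adjusted p = 1.64e-08) and the sterol biosynthesis list (1 of 24 fell, 9 over the list alone, camera adjusted p = 5.61e-08) moved down. The liver and yolk list moved down with 0 of 16 genes past the threshold over all genes and 12 over the list alone (camera adjusted p = 1.67e-16, and 0.0255 with an estimated correlation). The fit called 52 features with 3 arrays against 3, 25 higher and 27 lower, and 70 with slide as a block. The calls of thrb, gngt2b and xdh are unstable. A gene with a clone name, si:ch211-103n10.5, chosen after its values were seen, rose with all 4 of these chemicals: by 4.68 ± 0.38 with Tiratricol, 3.65 ± 0.38 with tetraiodothyroacetic acid, 5.13 ± 0.45 with triiodothyronine and 4.62 ± 0.41 with CP-634384. It kept these calls without each array in turn.

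**Figure D2:**
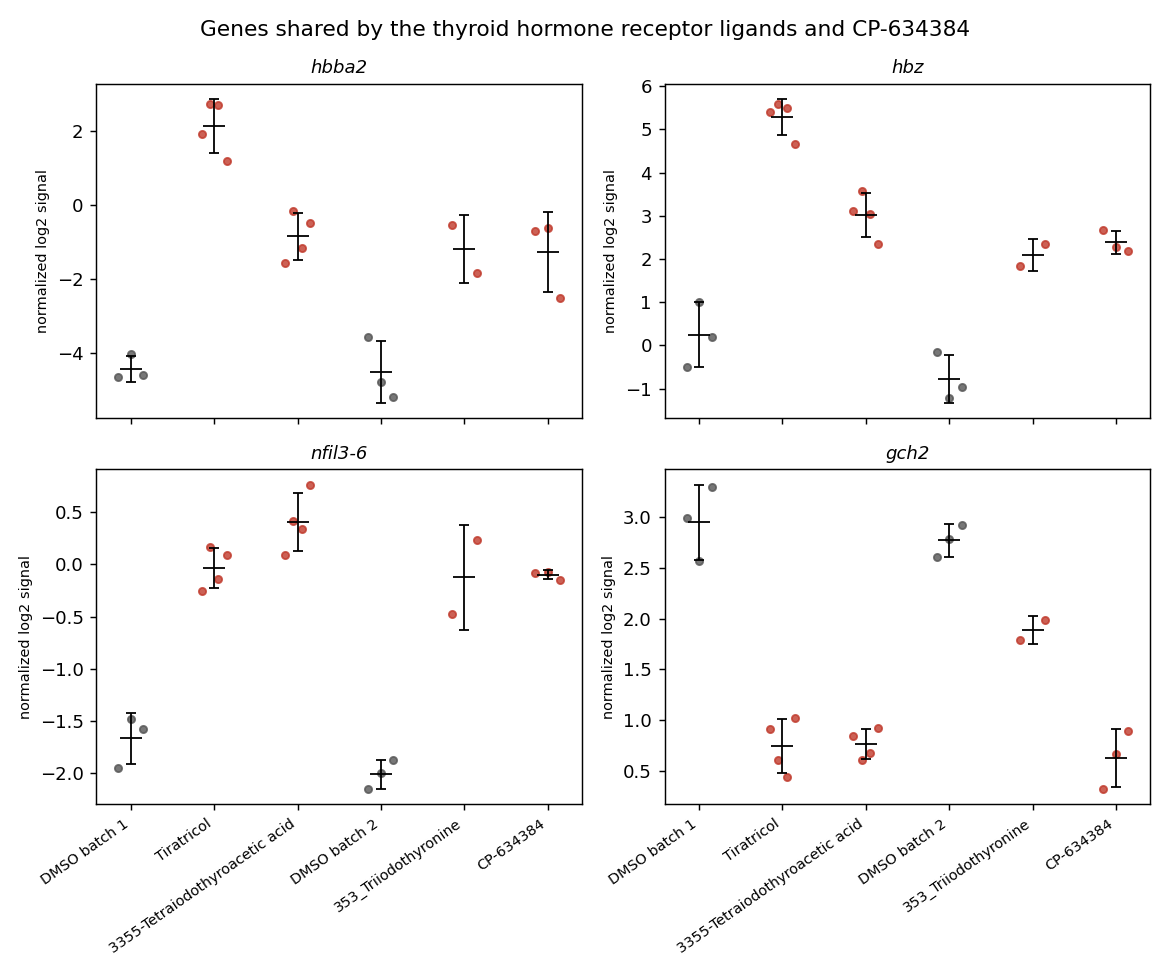
Each point is 1 array, on an axis of normalized log2 signal (log2 minus the 75th percentile of the array), for hbba2, hbz, nfil3-6 and gch2; the black lines are the group mean ± 1 SD. DMSO arrays are grey. In the 4 exposed groups hbba2, hbz and nfil3-6 lie above both DMSO groups and gch2 lies below them, which for gch2 with 353_Triiodothyronine did not pass the test.

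Among the steroid estrogens, estradiol (17B_estradiol) lowered fkbp5, a steroid receptor co-chaperone induced by glucocorticoids and androgens, by -3.00 ± 0.31 (8.01-fold lower, adjusted p = 1.95e-10). It also lowered hpxa (hemopexin; at least 3.78-fold lower, not well above background on its 4 arrays), epd (-2.79 ± 0.32), uox, urate oxidase (-2.45 ± 0.31), and the liver fatty acid carrier fabp10a (-2.32 ± 0.25). The immediate early genes nfkbiaa (-0.89 ± 0.14), fosab (-1.68 ± 0.28) and socs3a (-1.33 ± 0.23) were lower than the high DMSO level of batch 1. Of the androgen list 1 of 6 genes fell, fkbp5 (1 over the list alone, camera adjusted p = 0.000902), and of the glucocorticoid list 1 of 11, again fkbp5 (2 over the list alone, camera adjusted p = 0.0227), with a median of 0.01 and a mean of -0.38. The brain aromatase gene cyp19a1b, a marker of estrogen action, was well above background and measured 0.06 with a 95% interval of -0.49 to 0.62 for estradiol. The fit called 226 features with 4 arrays against 3, 70 higher and 156 lower, 242 with slide as a block, and 57 to 548 without 1 array. Its 41 rises over 2-fold were all features without a gene name, and the named rises, hist1h2a10 (0.78 ± 0.18), tmem185 (0.78 ± 0.20) and hist2h3c (0.73 ± 0.17), are unstable, as are fosab and hpxa. With normexp 52.1% of the calls were higher, and with quantile normalization 5.88%.

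Ethinylestradiol (17alpha_Ethinylestradiol) raised ghrh, growth hormone releasing hormone (3.04 ± 0.42, adjusted p = 3.7e-07), cdkn1a, a cell cycle inhibitor (2.17 ± 0.26) and p2rx8 (2.13 ± 0.58, unstable, 0.77 with normexp and 0.488 with the deposited values). It lowered fabp10a (-2.98 ± 0.25), epd (-2.98 ± 0.32) and rs1a, retinoschisin (-2.30 ± 0.27). In the photoreceptor list 7 of 15 genes fell, with opn1lw2 (-2.23 ± 0.37), rcvrna (-1.08 ± 0.18) and arr3a (-1.17 ± 0.22) among them (9 over the list alone, camera adjusted p = 1.48e-10). The inflammation and immediate early list moved up (4 of 16 rose, 7 over the list alone, camera adjusted p = 5.3e-08), with fosab at 2.02 ± 0.28, mmp9 at 2.02 ± 0.34 and irg1l at 1.26 ± 0.27. The xenobiotic oxidase gene cyp1a rose by 0.999 ± 0.22 (unstable) and the aryl hydrocarbon list moved up (1 of 10, 4 over the list alone, camera adjusted p = 0.00836). The value of cyp19a1b was -0.45, with an interval of -0.999 to 0.11. The fit called 394 features with 4 arrays against 3, 149 higher and 245 lower, 471 with slide as a block, and 171 to 389 without 1 array.

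Genistein, an isoflavone, raised cdkn1a by 4.79 ± 0.26 (27.7-fold, adjusted p = 7e-27), phlda3 by 2.54 ± 0.19 and gadd45aa by 2.53 ± 0.19. The interferon-induced gene isg15 (4.19 ± 0.41) and fosab (3.61 ± 0.28) rose as well. The falls were led by plekhs1.3 (-2.70 ± 0.38, unstable, -0.0555 with normexp), fabp10a (-2.38 ± 0.25) and uox (-2.34 ± 0.31). The replication and division genes mcm2 (-0.78 ± 0.15), cdc20 (-0.88 ± 0.19, unstable) and mcm5 (-0.78 ± 0.18) fell, and the cell cycle list had 6 of 21 genes lower (7 over the list alone, camera adjusted p = 7.44e-05, and 0.344 with an estimated correlation). The fit called 1187 features with 4 arrays against 3, 715 higher and 472 lower, and 1969 with slide as a block. Of the 216 rises over 2-fold, 171 had no gene name. The share of higher calls was 60.2%, against 74.6% with normexp. Without DMSO batch 2 replicate 1 the count was 236.

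Bisphenol A (Bisphenol_A) raised cyp1a by 3.12 ± 0.22 (8.71-fold, adjusted p = 5.36e-19), dhrs13l1 by 1.32 ± 0.21 and the glucuronosyltransferase ugt1ab by 1.27 ± 0.18. The aryl hydrocarbon list moved up with 1 of 10 genes past the threshold (2 over the list alone with 1 the other way, camera adjusted p = 0.000404). The antioxidant genes gstp1.1 (1.01 ± 0.17), gstp1.2 (0.95 ± 0.17) and prdx1 (0.90 ± 0.23, unstable) rose. The falls were led by muc5b, a mucin (-2.78 ± 0.36), fosab (-2.73 ± 0.28) and ponzr3 (-2.53 ± 0.29), with nfkbiaa at -0.91 ± 0.14. The glucocorticoid list moved down (3 of 11, 3 over the list alone, camera adjusted p = 0.00793), through fkbp5 (-2.02 ± 0.31), sgk1 (-0.68 ± 0.16) and hsd11b2 (-0.67 ± 0.18), of which the latter 2 are unstable. This list call was lost with the deposited values (adjusted p = 0.0869). The fit called 409 features with 4 arrays against 3, 78 higher and 331 lower, and 618 with slide as a block. Without DMSO batch 1 replicate 5 the count was 95.

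Bisphenol AF (Bisphenol_AF), which carries trifluoromethyl groups where bisphenol A has methyl groups, lowered fkbp5 by -4.39 ± 0.29 (20.9-fold lower, adjusted p = 8.99e-21), ponzr3 by -2.35 ± 0.27 and dhrs13a.2 by -1.47 ± 0.20. It raised the collagen chaperone gene serpinh1b (1.48 ± 0.19), plekhf1 (1.05 ± 0.18) and tcima (0.88 ± 0.18). The androgen list (1 of 6) and the glucocorticoid list (1 of 11) moved down with fkbp5 as their 1 called gene (1 each over the list alone, camera adjusted p = 0.000222 and 0.000652), and the androgen list call was lost with the deposited values (adjusted p = 0.0631). The clock list moved down (2 of 19, 3 over the list alone, camera adjusted p = 0.00659) through nr1d2a (-1.02 ± 0.17) and tefb (-0.93 ± 0.17). The cell cycle list moved up, 1 of 21 genes over all genes (top2a, 0.49 ± 0.11) and 14 over the list alone (camera adjusted p = 6.32e-18). The unfolded protein list also moved up (1 of 19, dnajb9b at 0.76 ± 0.17, 6 over the list alone, camera adjusted p = 2.43e-06). The heat shock list moved up (1 of 16, 2 over the list alone, camera adjusted p = 3.03e-06), a call lost with slide as a block (adjusted p = 0.0888). The fit called 86 features with 4 arrays against 4, 35 higher and 51 lower, and 117 with slide as a block. The calls of top2a and dnajb9b are unstable, and the share of higher calls was 40.7%, against 58.4% with normexp.

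Butylparaben and Propylparaben lowered liver genes. With Butylparaben 9 of 16 genes of the liver and yolk list fell (13 over the list alone, camera adjusted p = 1.45e-48) and with Propylparaben 13 (14 over the list alone, camera adjusted p = 3.24e-52). Butylparaben lowered apoa4a, an apolipoprotein (-4.36 ± 0.35, 20.5-fold lower, adjusted p = 1.43e-16), cyp4v2a (at least 3.81-fold lower, not well above background on its 4 arrays), hp, haptoglobin (-3.11 ± 0.24), vtnb, vitronectin (-2.46 ± 0.24), and the fibrinogen chains fgb (-2.35 ± 0.25) and fgg (-2.15 ± 0.26). The cartilage matrix gene matn1 fell by -3.05 ± 0.25, and the cartilage list moved down (1 of 16, 3 over the list alone, camera adjusted p = 0.000136). In the photoreceptor list arr3a (-1.43 ± 0.21) and gngt1 (-1.01 ± 0.20) fell, 2 of 15 (4 over the list alone, camera adjusted p = 3.92e-10). The sterol list moved down (3 of 24, 6 over the list alone, camera adjusted p = 7.46e-06), with fdps at -0.75 ± 0.15. The androgen list moved down (1 of 6, fkbp5 at -2.34 ± 0.29, 2 over the list alone, camera adjusted p = 0.0031), a call lost with slide as a block (adjusted p = 0.0727) and with the deposited values (0.0869). The egg yolk precursor gene vtg6 rose by 1.69 ± 0.37, and vox (1.16 ± 0.29) and ctsba (1.16 ± 0.31) rose with unstable calls. The fit called 430 features with 4 arrays against 4, 47 higher and 383 lower, and 630 with slide as a block. With the deposited values 2110 were higher and 2255 lower.

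Propylparaben lowered matn1 by -4.80 ± 0.25 (27.8-fold lower, adjusted p = 2.79e-27), apoa4a by -3.86 ± 0.35 and uox by -3.46 ± 0.28, and cyp4v2a at least 4.01-fold. The liver genes vtnb (-2.91 ± 0.24), cp, ceruloplasmin (-2.28 ± 0.24) and fgg (-2.28 ± 0.26) fell. The photoreceptor list had 4 of 15 genes lower (5 over the list alone, camera adjusted p = 3.73e-11), with arr3a at -1.93 ± 0.21 and opn1lw2 at -2.11 ± 0.34. The cartilage list had 4 of 16 lower (4 over the list alone, camera adjusted p = 1.85e-09), with col9a1a at -1.15 ± 0.18. The rises were led by ctsll (1.48 ± 0.32), vtg6 (1.42 ± 0.37, unstable) and the hatching gland protease gene ctslb (1.31 ± 0.30), and the hatching enzyme gene he1.1 rose with an unstable call. The gene cyp1a rose by 1.01 ± 0.20. The fit called 667 features with 4 arrays against 4, 91 higher and 576 lower, and 1263 with slide as a block. With the deposited values 1828 were higher and 2386 lower. With both parabens the estrogen list moved up with 1 of 15 genes called (3 and 2 over the list alone, camera adjusted p = 0.0102 for Butylparaben and 0.0331 for Propylparaben). The values were adjusted p = 0.241 and 0.344 with an estimated correlation.

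Kepone (chlordecone) raised lepa, leptin (4.26 ± 0.58, 19.2-fold, adjusted p = 3.09e-07), the muscle gene tcap (4.19 ± 0.47), pth1a (3.86 ± 0.58) and the small heat shock gene hspb9 (2.86 ± 0.35). The heat shock list moved up (3 of 16, 7 over the list alone, camera adjusted p = 2.17e-07), with hspb11 at 2.41 ± 0.26, dnajb1b at 0.96 ± 0.17 and the co-chaperone bag3 at 0.94 ± 0.19. The sterol list moved up (4 of 24, 7 over the list alone, camera adjusted p = 6.19e-07), with sqlea at 0.86 ± 0.16 and mvda at 0.59 ± 0.15 (unstable). The falls were led by ankrd1b (-1.89 ± 0.26), otos2 (-1.51 ± 0.20) and pmaip1 (at least 1.47-fold lower, unstable). The fit called 984 features with 3 arrays against 3, 314 higher and 670 lower, and 1040 with slide as a block. Of the 217 rises over 2-fold, 86 had no gene name, and 11 of the other 104 arrays stood as high over the 217 as the lowest Kepone array. Without DMSO batch 1 replicate 1 the count was 147.

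Raloxifene, a selective estrogen receptor modulator, lowered the clock genes per1b (-2.17 ± 0.23, adjusted p = 1.22e-10), cry1a (-2.14 ± 0.18) and cry3b (-1.01 ± 0.17). The falls of per1b and cry1a were called in all 4 chemicals of batch 4 and in 0 of the other 21, so a difference of the batch between exposed and DMSO dishes is not excluded. The clock list had 4 of 19 genes lower (8 over the list alone, camera adjusted p = 9.01e-13), with per3 at -0.82 ± 0.16 and nr1d2b at -0.75 ± 0.16, both unstable. The named rises were fosab (1.36 ± 0.28), rgs2 (1.16 ± 0.25) and sik1 (1.14 ± 0.20), all unstable, and nfkbiaa rose by 0.91 ± 0.14. The fit called 76 features with 3 arrays against 4, 65 higher and 11 lower, 90 with slide as a block, and 15 to 130 without 1 array. With the deposited values 591 were higher and 1001 lower, and with pooled DMSO arrays 0 were higher and 22 lower. Of the 57 rises over 2-fold, 51 had no gene name, and other splits of the same 7 arrays called more features than the real one.

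Methyltestosterone (17_Methyltestosterone) lowered photoreceptor genes. In that list 7 of 15 genes fell (10 over the list alone with 2 the other way, camera adjusted p = 6.96e-17), with opn1lw2 at -4.36 ± 0.37 (20.6-fold lower, adjusted p = 1.62e-15) and arr3a at -2.07 ± 0.22. The cone gene gnb3a (-4.36 ± 0.33), matn1 (-4.17 ± 0.27) and rs1a (-3.82 ± 0.27) fell. In the nervous system list 8 of 15 genes fell (9 over the list alone, camera adjusted p = 3.1e-10), with neurod1 at -1.42 ± 0.20, gad1b at -0.72 ± 0.12 and elavl4 at -0.68 ± 0.15. The cartilage list moved down (3 of 16, 3 over the list alone, camera adjusted p = 0.00119). The rises were led by ghrh (3.02 ± 0.42), isg15 (2.39 ± 0.41), cdkn1a (2.35 ± 0.26) and bmb (2.23 ± 0.24). The sterol list had 10 of 24 higher (14 over the list alone, camera adjusted p = 1.48e-12), with sqlea at 1.51 ± 0.15, lss at 1.15 ± 0.22 and hsd17b7 at 1.04 ± 0.20. The cell cycle list had 10 of 21 higher, with ccnd1 at 0.87 ± 0.16 and rrm2 at 1.03 ± 0.20 (17 over the list alone, camera adjusted p = 1.01e-11, and 0.0517 with an estimated correlation). The gene fkbp5 fell by -1.13 ± 0.31 (unstable). The fit called 2140 features with 4 arrays against 3, 819 higher and 1321 lower, and 3609 with slide as a block.

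Dihydrotestosterone (5alpha_Dihydrotestosterone) raised the sterol biosynthesis pathway: 15 of 24 genes rose, and 17 over the list alone (camera adjusted p = 2.06e-93). They included lss (3.30 ± 0.20), sqlea, squalene epoxidase (2.83 ± 0.14, 7.12-fold, adjusted p = 2.59e-29), nsdhl (2.57 ± 0.20), hmgcs1 (2.57 ± 0.14) and mvda (2.21 ± 0.13). The fatty acid desaturase gene fads2 rose by 3.44 ± 0.20, and abca1a, a cholesterol exporter, fell by -2.03 ± 0.19. The gene fkbp5 fell by -3.19 ± 0.29 (9.11-fold lower) and was the 1 called gene of the 6 in the androgen list (1 over the list alone, camera adjusted p = 9.94e-05). The genes epd (-2.13 ± 0.30) and ponzr3 (-1.95 ± 0.27) fell. In the clock list 7 of 19 genes fell (8 over the list alone, camera adjusted p = 1.03e-10), with per1b at -1.45 ± 0.21, cry1a at -1.24 ± 0.17 and tefb at -1.17 ± 0.17. The photoreceptor list moved down (2 of 15, 5 over the list alone, camera adjusted p = 1.16e-07, opn1lw2 at -1.41 ± 0.34, unstable). The fit called 260 features with 4 arrays against 4, 131 higher and 129 lower, and 366 with slide as a block, 132 higher and 234 lower. With the deposited values 954 were higher and 2256 lower.

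Vinclozolin, a fungicide and androgen receptor antagonist, lowered fkbp5 by -4.51 ± 0.29 (22.8-fold lower, adjusted p = 1.62e-21), ponzr3 by -2.34 ± 0.27 and klf3 by -1.31 ± 0.16. It raised cyp1a by 2.22 ± 0.20 (4.65-fold, adjusted p = 2.38e-13), serpinh1b by 1.11 ± 0.19 and arrdc3b by 1.07 ± 0.19. The androgen list (1 of 6, 1 over the list alone, camera adjusted p = 3.79e-08) and the glucocorticoid list (1 of 11, 2 over the list alone, camera adjusted p = 5.03e-05) moved down with fkbp5 as their 1 called gene. The aryl hydrocarbon list moved up with cyp1a as its 1 called gene of 10 (1 over the list alone, camera adjusted p = 0.0076), with a median of -0.02 and a mean of 0.19. The clock list had 2 of 19 lower, tefb (-1.12 ± 0.17) and nr1d2a (-0.92 ± 0.17; 2 over the list alone, camera adjusted p = 0.000256). The fit called 39 features with 4 arrays against 4, 8 higher and 31 lower, and 84 with slide as a block.

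Propiconazole, an azole fungicide, raised cyp1a by 4.09 ± 0.22 (17.0-fold, adjusted p = 3.19e-26), pth1a by 2.18 ± 0.54 (unstable, 0.572 with normexp), hspb9 by 1.44 ± 0.33 (unstable) and cyp26a1 by 1.15 ± 0.19. It lowered fkbp5 by -3.44 ± 0.31 (10.9-fold lower, adjusted p = 1.67e-13), ponzr3 by -3.03 ± 0.29 and dhrs13a.2 by -2.10 ± 0.21, and nfkbiaa by -0.92 ± 0.14. The androgen list (1 of 6, 1 over the list alone, camera adjusted p = 2.51e-06) and the glucocorticoid list (1 of 11, 2 over the list alone, camera adjusted p = 2.17e-07) moved down with fkbp5 as their 1 called gene. The aryl hydrocarbon list moved up (1 of 10, 3 over the list alone, camera adjusted p = 6.76e-06) and the leukocyte list down (1 of 12, lyz, lysozyme, at -1.16 ± 0.21, 3 over the list alone, camera adjusted p = 3.41e-07). The fit called 106 features with 4 arrays against 3, 19 higher and 87 lower, and 172 with slide as a block. On Zv9 fkbp5 lies on chromosome 6 at 41026922 to 41046917 and cyp1a on chromosome 18 at 4974676 to 4985566, each measured by 1 probe.

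**Figure D3:**
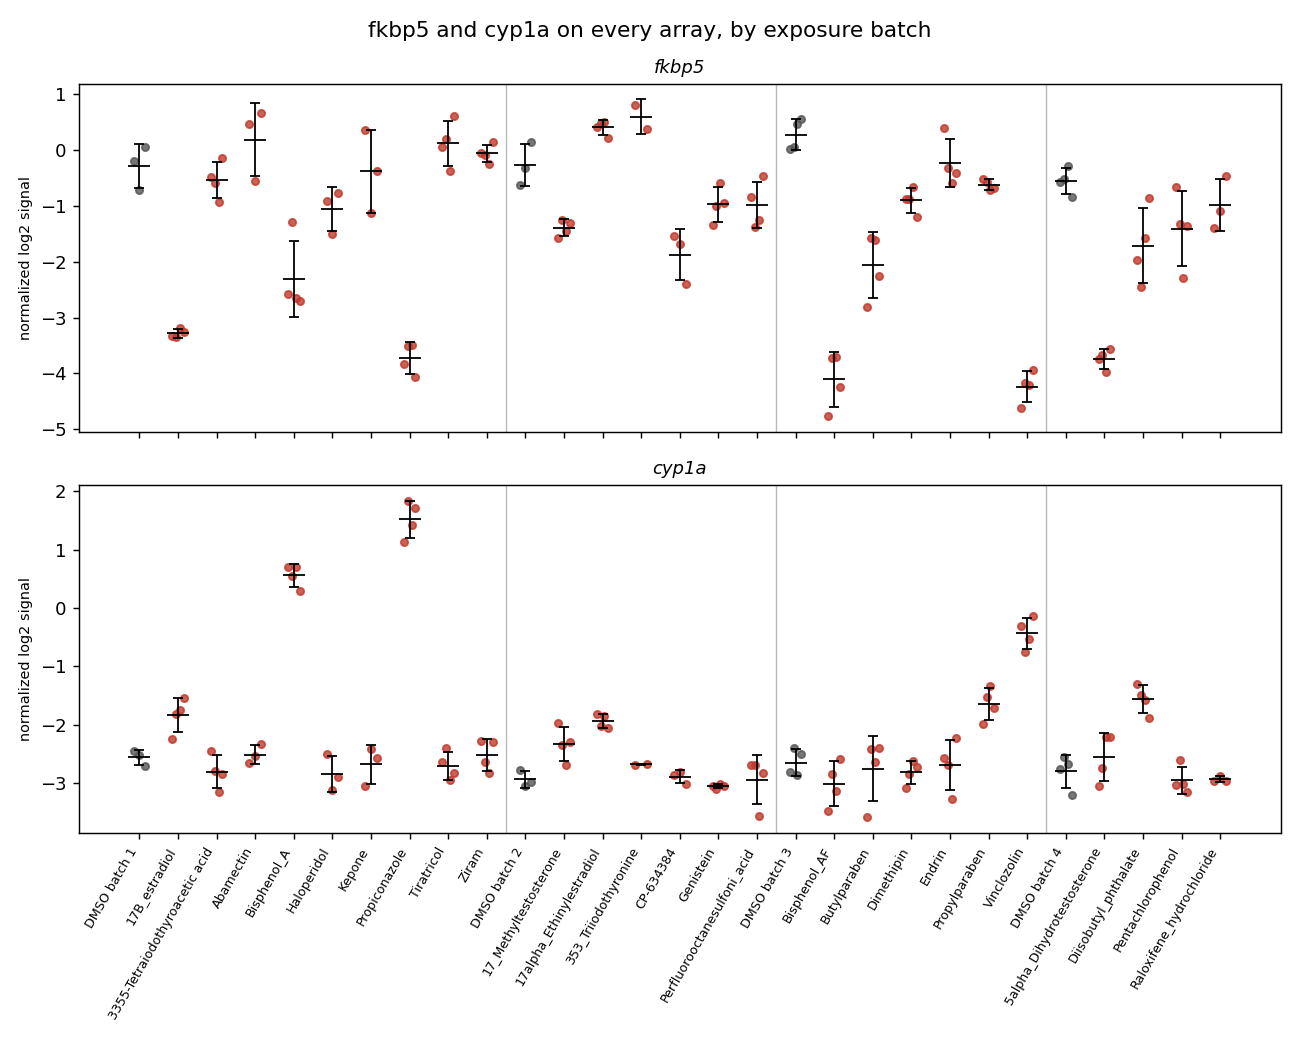
Each point is 1 array, on an axis of normalized log2 signal, for fkbp5 and cyp1a, with the groups in the order of the exposure batches (grey lines between batches) and DMSO in grey; black lines are the group mean ± 1 SD. The group means of fkbp5 were called lower than DMSO in 10 of the 25 chemicals and those of cyp1a higher in 6.

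Diisobutyl phthalate (Diisobutyl_phthalate) changed the most features in the main fit, while with the deposited values Haloperidol (9177) and Pentachlorophenol (8862) had more than its 8833. The interferon gene ifnphi1 rose at least 4.54-fold (adjusted p = 1.98e-08, not well above background in its DMSO arrays), isg15 by 3.00 ± 0.38 and mdp1 by 2.96 ± 0.30. The sterol list had 14 of 24 genes higher (14 over the list alone, camera adjusted p = 7.37e-17), with hmgcs1 at 1.76 ± 0.14, sqlea at 1.59 ± 0.14 and lss at 1.91 ± 0.20. The unfolded protein and integrated stress list had 8 of 19 higher (8 over the list alone, camera adjusted p = 2.23e-05), with atf3 at 1.89 ± 0.21, chac1 at 0.91 ± 0.15 and atf5b at 1.34 ± 0.25. The heat shock gene hspb11 (1.49 ± 0.23), serpinh1b (1.17 ± 0.19), socs3a (1.46 ± 0.21) and the vascular genes stab2 (1.07 ± 0.16) and tie1 (0.998 ± 0.13) rose, and cyp1a rose by 1.24 ± 0.20. The falls were led by ccl34b.1 (-3.67 ± 0.19), epd (-3.54 ± 0.30) and smpdl3b (-2.83 ± 0.27), with fkbp5 at -1.16 ± 0.29. The photoreceptor list had 7 of 15 lower (9 over the list alone, camera adjusted p = 2.83e-08), with arr3a at -1.52 ± 0.21 and opn1lw2 at -1.93 ± 0.34. The cartilage list had 8 of 16 lower (8 over the list alone, camera adjusted p = 0.000133), with matn1 at -2.50 ± 0.25 and col2a1a at -0.67 ± 0.15. The fit called 4187 features with 4 arrays against 4, 2552 higher and 1635 lower, and 3850 with slide as a block. The share of higher calls was 61.0%, against 75.6% with normexp.

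Pentachlorophenol, an uncoupler of oxidative phosphorylation, lowered photoreceptor genes, 7 of 15 (9 over the list alone, camera adjusted p = 7.37e-17), with arr3a at -1.96 ± 0.21 and rcvrna at -1.24 ± 0.17. The genes rs1a (-3.05 ± 0.25), gngt2b (-3.02 ± 0.30), gnb3a (-3.02 ± 0.31) and matn1 (-3.00 ± 0.25) gave the largest falls. The rises were led by igfbp1b (1.98 ± 0.30), agxtb (1.91 ± 0.33) and the kinase gene pim2 (1.55 ± 0.18). In the clock list 3 of 19 genes fell (7 over the list alone, camera adjusted p = 1.1e-06), per1b (-1.88 ± 0.21), cry1a (-1.40 ± 0.17) and nr1d2b (-0.82 ± 0.15). In the sterol list 7 of 24 fell (10 over the list alone, camera adjusted p = 5.25e-07), with hmgcs1 at -0.69 ± 0.14, ebp at -0.83 ± 0.19 (unstable) and mvda at -0.53 ± 0.13. The lens list moved down (3 of 15, 7 over the list alone, camera adjusted p = 2.17e-07). The fit called 1287 features with 4 arrays against 4, 435 higher and 852 lower, and 3554 with slide as a block.

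Haloperidol, a dopamine receptor antagonist, lowered eye genes. In the lens list 9 of 15 crystallin and related genes fell (13 over the list alone, camera adjusted p = 6.91e-18), with crygm3 at -1.21 ± 0.16, cryba1b at -0.90 ± 0.13 and cryaa at -1.26 ± 0.19. In the photoreceptor list 7 of 15 fell (8 over the list alone, camera adjusted p = 6.36e-11), with rcvrna at -1.83 ± 0.19 and the transcription factor crx at -1.35 ± 0.20. The largest falls were gngt2b (-3.42 ± 0.35, 10.7-fold lower, adjusted p = 2.98e-11), opn1lw2 (-3.11 ± 0.40) and crygmxl1 (-2.82 ± 0.33). The sterol list had 6 of 24 higher (13 over the list alone, camera adjusted p = 9.5e-11), with sqlea at 1.26 ± 0.16, hmgcs1 at 0.94 ± 0.16 and lss at 1.33 ± 0.24. The largest rises, trim35-34 (2.48 ± 0.72), fpr1 (2.14 ± 0.55) and slc50a1 (2.06 ± 0.56), are unstable. The fit called 793 features with 3 arrays against 3, 156 higher and 637 lower, 2530 with slide as a block, and 346 to 889 without 1 array.

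Dimethipin, a defoliant, raised nupr1b (2.22 ± 0.17, 4.65-fold, adjusted p = 2.25e-16), aifm4 (1.66 ± 0.15) and the Nrf2 targets prdx1 (1.57 ± 0.21), gstp1.2 (1.45 ± 0.16), gstp1.1 (1.45 ± 0.16) and gsr (1.43 ± 0.16). The Nrf2 list had 6 of 19 genes higher, and 10 higher and 1 lower over the list alone (camera adjusted p = 2.62e-36). The unfolded protein list moved up with 0 of 19 called (3 over the list alone, camera adjusted p = 8.5e-05). Of 55 features 53 were higher, and 44 were called with slide as a block. Endrin, an organochlorine like Kepone, raised lepa (at least 5.62-fold, not well above background in its DMSO arrays), pth1a (2.52 ± 0.50, 0.619 with normexp), hspb9 (2.30 ± 0.30) and tcap (2.24 ± 0.41). The heat shock list moved up (1 of 16, hspb11 at 1.57 ± 0.23, 3 over the list alone, camera adjusted p = 4.64e-09) and so did the unfolded protein list (1 of 19, dnajb9b at 0.74 ± 0.17, 3 over the list alone, camera adjusted p = 1.45e-05). The aryl hydrocarbon list moved down with 0 of 10 called (0 over the list alone, camera adjusted p = 0.0105). Falls were led by g6pc1a.2 (-1.25 ± 0.25), diabloa (-1.24 ± 0.28) and txnipb (-1.07 ± 0.20). Endrin called 52 features, and 68 with slide as a block; lepa, pth1a, diabloa and dnajb9b are unstable.

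Perfluorooctanesulfonic acid (Perfluorooctanesulfoni_acid) raised fosab (2.09 ± 0.28, adjusted p = 2.06e-06), socs3a (1.41 ± 0.23), gfra1a (1.34 ± 0.31) and nfkbiaa (1.15 ± 0.14). It lowered rsrp1 (-1.26 ± 0.25) and the titin genes ttnb (-1.11 ± 0.23) and ttna (-1.04 ± 0.23). It called 64 features, 18 higher and 46 lower. With slide as a block it called 55, of which 42 were higher and 13 lower, and 21 were shared with the 64. Of these 7 genes gfra1a, rsrp1, ttnb and ttna are unstable, and the fosab call was lost with pooled DMSO arrays. Without DMSO batch 2 replicate 1 the count was 7. Ziram, a dithiocarbamate fungicide, raised clu, clusterin (1.54 ± 0.25, adjusted p = 0.000254), tgm2l (1.13 ± 0.17) and arpp21 (1.01 ± 0.18, unstable). The genes arrdc3b (-1.54 ± 0.21), tcima (-1.45 ± 0.19), nfkbiaa (-1.03 ± 0.14) and fosab (-1.34 ± 0.28, unstable) were lower than DMSO batch 1. The sterol list moved up (1 of 24, hmgcs1 at 0.76 ± 0.15, unstable, and 6 over the list alone; camera adjusted p = 6.48e-17). Ziram called 13 features, 6 higher and 7 lower, and 29 with slide as a block. Abamectin lowered fosab (-1.62 ± 0.30) and tcima (-1.21 ± 0.21), its 2 called features and both unstable, with 563 features at an unadjusted p under 0.05 and 1 called with slide as a block.

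Structurally related chemicals were compared at their own EC80 doses, which differ. In the same batch, Butylparaben and Propylparaben differ by 1 carbon of the ester chain. They differed in 15 features, and in 30 with slide as a block. Butylparaben lowered dhrs13a.2 (-1.55, against 0.01 for Propylparaben; difference -1.56 ± 0.20, 95% interval -1.96 to -1.17, adjusted p = 5.88e-07), ankrd9 and fkbp5 (-2.34, against -0.89 for Propylparaben, which was not called; difference -1.44 ± 0.29, lost with slide as a block). It left matn1 less reduced (difference 1.74 ± 0.25), and cyp1a (difference -1.11 ± 0.20) and nfkbiaa (difference -0.69 ± 0.13) were lower. The differences of ankrd9, cyp1a, nfkbiaa and fkbp5 are unstable. The difference in vtg6 was 0.26, with an interval of -0.47 to 0.998. The 2 parabens shared 21 rises and 307 falls, where independent lists of those sizes would share 0.10 and 5.30. Across genes, which are not independent replicates, the fold changes had r = 0.53 and a covariance of 0.05. Simulated unchanged groups against the same 4 DMSO arrays gave r = 0.46 and a covariance of 0.05. With the 4 DMSO arrays split between the 2 chemicals, r was 0.16.

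Tetraiodothyroacetic acid carries 1 more iodine than Tiratricol, in the same batch. They differed in 240 features (46 higher, 194 lower), and in 766 with slide as a block. With tetraiodothyroacetic acid hbz (difference -2.27 ± 0.25, interval -2.77 to -1.77, adjusted p = 9.16e-10) and hbba2 (-2.98 ± 0.36) were lower than with Tiratricol, and brd2a (-0.89 ± 0.11) and foxq2 (-0.84 ± 0.13) too. The genes nfkbiaa (1.33 ± 0.13), arrdc3b (1.82 ± 0.19) and klf11b (0.87 ± 0.14) were higher. The difference in gch2 was 0.01 (interval -0.32 to 0.35) and in dio3a 0.46 (interval 0.13 to 0.79, adjusted p = 0.167; called with the deposited values, at 0.247). They shared 17 rises and 14 falls, where independent lists would share 0.02 and 0.03. Across genes r was 0.45, against 0.57 in simulated unchanged groups, with covariances of 0.05 and 0.07. The 3 shared DMSO arrays add likeness of this kind, and a fit with them split between the 2 chemicals was not run. The count fell to 25 without Tiratricol replicate 1 and rose to 1715 without Tiratricol replicate 3.

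For pairs in different batches, each chemical was first set against its own DMSO arrays. Triiodothyronine and Tiratricol differed in 11 features, and in 14 with slide as a block. They shared 12 rises, where independent lists would share 0.01. In triiodothyronine hbba2 (difference -3.23 ± 0.60, interval -4.43 to -2.03) and hbz (-2.18 ± 0.43) were lower, and nfkbiaa (1.39 ± 0.22), fosab (2.83 ± 0.44), arrdc3b (1.84 ± 0.33) and tcima (1.61 ± 0.30) were higher; the calls of hbba2, hbz, arrdc3b and tcima were lost without at least 1 array. The 6 immediate early genes averaged -1.22 with triiodothyronine and -1.57 with Tiratricol, and -1.53 and -0.12 in their DMSO arrays, so most of the difference over this set lies in the DMSO levels. Ethinylestradiol and estradiol, which differ by an ethinyl group, differed in 109 features, and in 110 with slide as a block. Here fosab (difference 3.70 ± 0.40), fkbp5 (3.68 ± 0.44, interval 2.80 to 4.55, adjusted p = 2.26e-08), socs3a (2.31 ± 0.33) and nfkbiaa (1.37 ± 0.20) were higher with ethinylestradiol. The 6 genes averaged -0.81 with ethinylestradiol and -0.91 with estradiol, against the same -1.53 and -0.12 in DMSO, so their difference too lies mostly in the DMSO levels. They shared 0 rises and 24 falls, against 0.25 and 0.92 for independent lists (r = 0.15).

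Bisphenol AF and bisphenol A differed in 120 features, and in 55 with slide as a block. The gene cyp1a, raised by bisphenol A, measured -0.37 with bisphenol AF (difference -3.49 ± 0.30, interval -4.09 to -2.89, adjusted p = 2.6e-14). The genes tcima (2.24 ± 0.26), fosab (2.73 ± 0.39) and serpinh1b (1.76 ± 0.28) were higher with bisphenol AF, and fkbp5 was lower (-2.37 ± 0.42). The 6 immediate early genes averaged -0.94 with bisphenol AF and -1.49 with bisphenol A, and -1.21 and -0.12 in their DMSO arrays, so the DMSO levels make up the larger part of the difference over this set. They shared 2 rises and 19 falls, where independent lists would share 0.07 and 0.41. Without DMSO batch 1 replicate 5 they differed in 23 features and without DMSO batch 1 replicate 2 in 504. Methyltestosterone, which has a 17-methyl group and a double bond where dihydrotestosterone has neither, differed from it in 869 features, and in 2503 with slide as a block. The sterol genes hmgcs1 (difference -1.79 ± 0.21, interval -2.20 to -1.37, adjusted p = 1.69e-08) and mvda (-1.57 ± 0.19) rose less with methyltestosterone. The gene cdkn1a (2.89 ± 0.35) was higher and matn1 (-3.08 ± 0.37) and pcdh8 (-1.78 ± 0.23) were lower. They shared 35 rises and 63 falls, where independent lists would share 2.58 and 4.09.

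Chemicals of the same receptor class were not found to be more alike than others over all genes. Across pairs from different batches, the mean correlation of fold changes across genes was -0.01 for the 34 pairs of one class (29 estrogen, 3 androgen and 2 thyroid, so almost all of 1 class) and -0.01 for the 194 other pairs. The difference was 0.000135 (permutation p = 0.997, two-sided, 100000 permutations of the class labels). Over the 8261 features called for at least 1 chemical, the difference was 0.04 (permutation p = 0.406), and with slide as a block 0.04 (permutation p = 0.236).

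Over all chemicals, 182 of the 775 list tests were called with the preset correlation of 0.01, 66 up and 116 down, and 68 with the estimated correlation. With slide as a block 193 were called. Lists described above as moved are among the 68 unless a p with an estimated correlation stands beside them as lost. The photoreceptor list was called down in 12 chemicals and up in 2, and in 9 with the estimated correlation. The liver and yolk list was called down in 13 and up in 2, and in 3 with the estimated correlation.

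**Figure D4:**
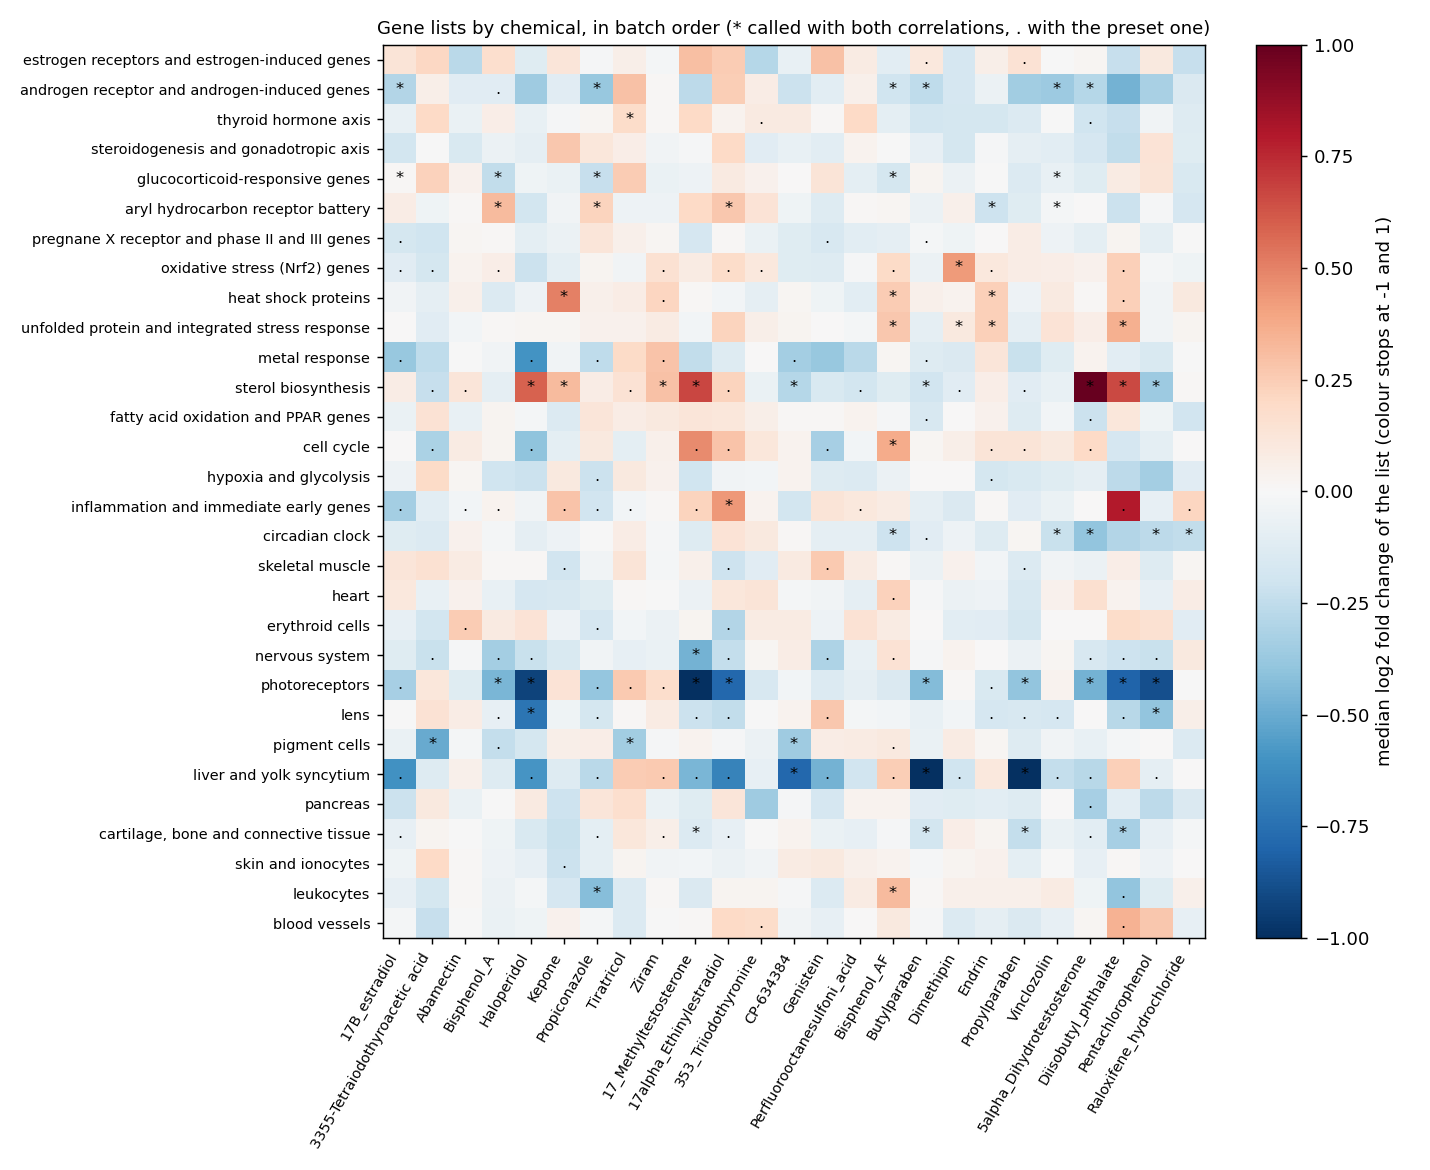
Colours give the median log2 fold change of each gene list (rows) in each chemical (columns, in batch order), from -1 in blue to 1 in red; values beyond are drawn at the end of the scale. The plot leaves out 1 of the lists. Stars mark tests called with both the preset and the estimated correlation, and dots those called with the preset one alone; the sterol list in 5alpha_Dihydrotestosterone is the strongest red and the photoreceptor and liver lists hold the strongest blues.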

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

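The tests of cry1a, per1b and ddb2 and of how many arrays of other groups stood as high were chosen after the result was seen. Those of the slide and the 6 immediate early genes were set before it, though these 6 were picked for their fold changes.

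For each named gene, the 4 arrays of each group of 4 were checked for an array far from the other 3, by its gap to the nearest array over the range of the group. Of 330 combinations of gene and group, 17 passed Dixon's critical value for 4 samples, which is 5.15%, and chance gives about 1 in 20. In DMSO batch 4 the lowest array was replicate 1 for abca1a (0.915), agxtb (0.853) and tefb (0.872), and the highest was replicate 4 for lss (0.888) and mdp1 (0.864). In DMSO batch 3 replicate 1 was lowest for apoa4a (0.833), cyp4v2a (0.851) and fgg (0.906), and replicate 2 was highest for gstp1.1 (0.832). Butylparaben replicate 3 was lowest for fgg (0.853) and hp (0.889), and Propylparaben replicate 5 for vtnb (0.913). Bisphenol A replicate 4 was highest for fkbp5 (0.908), at -1.28 against a mean of -2.64 in the other 3. Perfluorooctanesulfonic acid replicate 5 was highest for nfkbiaa (0.856), Tiratricol replicate 1 for opn1lw2 (0.881) and dihydrotestosterone replicate 3 for tefb (0.934). Bisphenol AF replicate 4 was lowest for ponzr3 (0.963).

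Immediate early and stress-induced genes were called lower in chemicals of batch 1 and higher in chemicals of batches 2 and 4. For fosab these were 7 of 9 chemicals in batch 1, 5 of 6 in batch 2 and 3 of 4 in batch 4. The DMSO arrays of batch 1 stood 1.32 ± 0.10 (log2, standard error) above the others over the 6 genes. They were picked for their fold changes, so this cannot test a high control. Of the 9 chemicals of batch 1, 0 had a mean below every DMSO array of batches 2 to 4 (lowest -1.93). Tiratricol alone (-1.57) lay below those of batches 2 and 3. A lowering below them, or from a level peculiar to batch 1 through handling or stage, stays open. The latter was not tested.

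The genes cry1a, per1b and ddb2 were called lower in all 4 chemicals of batch 4 and in 0 of the other 21. A high control is argued against, since the DMSO arrays of batch 4 stood lower than the other DMSO arrays by -0.29 ± 0.12 over the 3 genes. All 4 chemicals had a mean below each of the 14 DMSO arrays. An effect of these chemicals, or a difference in light or sampling time between the exposed and the DMSO dishes of that batch, could each give this, and the labels record neither. In diisobutyl phthalate the calls are uncertain: those of cry1a and per1b were lost with slide as a block and without each of 6 arrays, and that of ddb2 with normexp (-0.0982), with quantile normalization (-0.354) and without each of 4 arrays. The call of ddb2 in dihydrotestosterone was lost with normexp (-0.349), with quantile normalization (-0.628) and without 1 array.

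Rises over 2-fold in Genistein, estradiol and raloxifene were mostly features without a gene name. In Kepone 39.6% were, which is no excess, since 20765 of the 41640 tested features had a name. Arrays of other groups stood as high over the rises of each chemical as the lowest array of the chemical, in 11 of 104 arrays for Kepone, 32 of 103 for Genistein, 19 of 103 for estradiol and 22 of 104 for raloxifene. Slide explained a share of 0.353, 0.38 and 0.289 of the variance of other groups for Genistein, estradiol and raloxifene, above the 95th percentile of 1000 permutations (0.234, 0.231 and 0.233). For Kepone the share was 0.227 against 0.236, so an effect of slide cannot be told apart from none with these arrays. A technical shift of these features may therefore add to the rises, and an effect of the chemicals on part of them was not excluded.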

How the results depend on the processing

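All alternatives were set before the results were seen. Counts are numbers of called features, given where they lay outside 1.5 times those in the report. Of 294 genes named for a chemical, 293 kept their direction and their side of the threshold with no filter on dim probes, 281 with normexp, 272 with quantile normalization, 276 with slide as a block, 277 with the replicate block, 287 with the authors' values and 263 with pooled DMSO arrays. Of 36 genes named for a pair, 35 kept theirs with slide as a block or the authors' values, 36 with normexp, quantile normalization and no filter, and 34 with the replicate block, which ended the calls of hbba2 (-3.12) and hbz (-2.14) in triiodothyronine minus Tiratricol. Of the 68 list calls, 65 were kept with slide as a block and 64 with the authors' values. Lists called in all numbered 68 with the estimated correlation in place of the preset one. Without the filter every count stayed within 1.5 times its value.

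With normexp the counts outside 1.5 times were perfluorooctanesulfonic acid 38 and bisphenol AF minus bisphenol A 198. This background correction moved the median of all genes by 0.13 in estradiol and tetraiodothyroacetic acid, 0.10 in diisobutyl phthalate and 0.15 in Genistein. With quantile normalization the counts were estradiol 85, Abamectin 1, bisphenol AF 51, Dimethipin 31, Ziram 7, tetraiodothyroacetic acid minus Tiratricol 613 and bisphenol AF minus bisphenol A 72. The cause was not tested.

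Of the 13 calls lost with normexp, hpxa in estradiol, lepa in Endrin and pmaip1 in Kepone were not well above background on 1 side of their comparison, where the signal limits the fold. Others, such as ctsba in Butylparaben and per3 in raloxifene, were well above background on every array, so low signal does not account for all of the losses; the cause was not tested.

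With slide as a block the counts outside 1.5 times were methyltestosterone 3609, triiodothyronine 24, Abamectin 1, bisphenol A 618, Genistein 1969, Haloperidol 2530, Pentachlorophenol 3554, Propiconazole 172, Propylparaben 1263, Vinclozolin 84, Ziram 29, the DMSO batches 501, methyltestosterone minus dihydrotestosterone 2503, tetraiodothyroacetic acid minus Tiratricol 766, bisphenol AF minus bisphenol A 55 and Butylparaben minus Propylparaben 30. Arrays of different groups on the same slide had a mean correlation of deviations of 0.297, against -0.0166 on different slides, so the block removes a spread that the groups share. The value of cyp19a1b in estradiol became -0.0729. In triiodothyronine dio3a (1.08) and gch2 (-0.998) passed the threshold. Perfluorooctanesulfonic acid went from 28.1% of calls higher to 76.4%, and to 88.9% with the replicate block.

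The replicate number was tried as a block although it pairs no samples: arrays of the same batch and number had a mean correlation of 0.0131, against -0.00205 for other numbers. With this block the counts were Abamectin 1, Haloperidol 424, Kepone 546, perfluorooctanesulfonic acid 9, raloxifene 116 and triiodothyronine minus Tiratricol 7, and cyp19a1b in estradiol became -0.0897. The cause was not tested, and the block was not run for the DMSO batches.

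With the authors' values the counts were methyltestosterone 6727, ethinylestradiol 1752, estradiol 1688, tetraiodothyroacetic acid 4251, triiodothyronine 71, dihydrotestosterone 3210, Abamectin 56, bisphenol A 4723, bisphenol AF 1162, Butylparaben 4365, CP-634384 224, diisobutyl phthalate 8833, Dimethipin 173, Endrin 328, Genistein 4159, Haloperidol 9177, Kepone 4091, Pentachlorophenol 8862, perfluorooctanesulfonic acid 451, Propiconazole 535, Propylparaben 4214, raloxifene 1592, Tiratricol 450, Vinclozolin 588, Ziram 250, the DMSO batches 4127, methyltestosterone minus dihydrotestosterone 9064, ethinylestradiol minus estradiol 907, tetraiodothyroacetic acid minus Tiratricol 7917, triiodothyronine minus Tiratricol 82, bisphenol AF minus bisphenol A 3272 and Butylparaben minus Propylparaben 1788. The median residual standard deviation was 0.15 there, against 0.30, and arrays on the same slide had a mean correlation of -0.135, so the values look corrected for slide and the tests count that spread as removed. The share of higher calls moved by over 20 percentage points in dihydrotestosterone (50.4% to 29.7%), Abamectin (0% to 53.6%), bisphenol AF (40.7% to 70.8%), Butylparaben (10.9% to 48.3%), Haloperidol (19.7% to 44.7%), perfluorooctanesulfonic acid (28.1% to 49.2%), Propylparaben (13.6% to 43.4%), raloxifene (85.5% to 37.1%) and Ziram (46.2% to 72.4%). Of the calls, 48 of 48 in tetraiodothyroacetic acid and 3791 of 4187 in diisobutyl phthalate were shared. The value of cyp19a1b in ethinylestradiol was 0.0015.

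With all 14 DMSO arrays as 1 control the counts were ethinylestradiol 1386, estradiol 4153, tetraiodothyroacetic acid 1437, triiodothyronine 23, dihydrotestosterone 580, bisphenol A 1985, bisphenol AF 325, Butylparaben 946, CP-634384 98, diisobutyl phthalate 6823, Dimethipin 88, Endrin 113, Genistein 2393, Haloperidol 4479, Pentachlorophenol 5074, perfluorooctanesulfonic acid 9, Propiconazole 303, Propylparaben 1952, raloxifene 22, Tiratricol 129, Vinclozolin 275 and Ziram 34. More control arrays and differences between batches both enter here. The share of higher calls moved by over 20 percentage points in estradiol (31% to 60.4%), triiodothyronine (100% to 78.3%), Abamectin (0% to 66.7%), bisphenol A (19.1% to 43.4%), bisphenol AF (40.7% to 64%), Haloperidol (19.7% to 51.5%), perfluorooctanesulfonic acid (28.1% to 77.8%), raloxifene (85.5% to 0%), Tiratricol (50% to 70.5%), Vinclozolin (20.5% to 55.3%) and Ziram (46.2% to 82.4%). The value of fosab became 0.045 in estradiol, 0.0997 in Abamectin and 0.39 in Ziram, since DMSO batch 1 stood higher than the other DMSO arrays.

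For class similarity the difference was -0.0125 with Spearman correlation (permutation p = 0.696), and 0.06 with the authors' values (permutation p = 0.172). The cause was not tested.

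Leaving out each array in turn gave these ranges of counts: methyltestosterone 1299 to 2050, ethinylestradiol 171 to 389, estradiol 57 to 548, tetraiodothyroacetic acid 25 to 56, triiodothyronine 5 to 12, dihydrotestosterone 153 to 297, Abamectin 0 to 4, bisphenol A 95 to 603, bisphenol AF 44 to 79, Butylparaben 319 to 413, CP-634384 33 to 46, diisobutyl phthalate 2501 to 4796, Dimethipin 33 to 56, Endrin 35 to 52, Genistein 236 to 1005, Haloperidol 346 to 889, Kepone 147 to 695, Pentachlorophenol 770 to 1869, perfluorooctanesulfonic acid 7 to 60, Propiconazole 55 to 86, Propylparaben 447 to 646, raloxifene 15 to 130, Tiratricol 49 to 76, Vinclozolin 33 to 41, Ziram 8 to 15, the DMSO batches 199 to 2547, methyltestosterone minus dihydrotestosterone 498 to 1056, ethinylestradiol minus estradiol 70 to 140, tetraiodothyroacetic acid minus Tiratricol 25 to 1715, triiodothyronine minus Tiratricol 4 to 13, bisphenol AF minus bisphenol A 23 to 504 and Butylparaben minus Propylparaben 5 to 18. For triiodothyronine the lone array left is assumed to vary like the other groups. Of 330 named results, 67 lost their call without at least 1 array. The value of cyp19a1b in estradiol ranged from -0.0781 without DMSO batch 1 replicate 5 to 0.181 without DMSO batch 1 replicate 2, and was -0.0599 without replicate 3. The difference of gch2 between tetraiodothyroacetic acid and Tiratricol was -0.0124, -0.0401, -0.0866 and -0.0309 without tetraiodothyroacetic acid replicates 2 and 5 and Tiratricol replicates 3 and 5, and at its highest 0.106 without Tiratricol replicate 2.

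The arrays that moved a count by over 1.5 times were these, and beyond the loss of an array the cause was not tested. Without DMSO batch 1 replicate 1 the counts were estradiol 78, tetraiodothyroacetic acid 27, Abamectin 0, bisphenol A 116, Haloperidol 346, Kepone 147, Propiconazole 55, Tiratricol 49, Ziram 8 and bisphenol AF minus bisphenol A 31. Without DMSO batch 1 replicate 2 the counts were estradiol 135 and bisphenol AF minus bisphenol A 504. Without DMSO batch 1 replicate 5 the counts were estradiol 79, tetraiodothyroacetic acid 25, bisphenol A 95, Haloperidol 398, Kepone 283, Propiconazole 60, Tiratricol 49, ethinylestradiol minus estradiol 71 and bisphenol AF minus bisphenol A 23. Without DMSO batch 2 replicate 1 the counts were methyltestosterone 1332, Genistein 236, perfluorooctanesulfonic acid 7 and the DMSO batches 363. Without DMSO batch 2 replicate 2 the counts were Genistein 710, perfluorooctanesulfonic acid 8 and the DMSO batches 518. Without DMSO batch 2 replicate 3 the counts were methyltestosterone 1299, ethinylestradiol 171, CP-634384 33, Genistein 749, the DMSO batches 520 and methyltestosterone minus dihydrotestosterone 498. Without DMSO batch 3 replicate 1 the counts were bisphenol AF 56 and Dimethipin 35. Without DMSO batch 3 replicate 2 the counts were bisphenol AF 57, the DMSO batches 2029 and bisphenol AF minus bisphenol A 52. Without DMSO batch 3 replicate 3 or 4 the counts were bisphenol AF 45 or 44 and bisphenol AF minus bisphenol A 49. Without DMSO batch 4 replicate 1 the counts were raloxifene 36 and the DMSO batches 2547. Without DMSO batch 4 replicate 2 the counts were raloxifene 26 and the DMSO batches 311. Without DMSO batch 4 replicate 3 the counts were diisobutyl phthalate 2731, Pentachlorophenol 799, raloxifene 20 and the DMSO batches 440. Without DMSO batch 4 replicate 4 the counts were dihydrotestosterone 160, Pentachlorophenol 788, raloxifene 130 and the DMSO batches 199. For estradiol the count was 65 without replicate 1, 548 without replicate 2 and 57 without replicate 3. Without ethinylestradiol replicate 1 the count was 240 for it and 70 for ethinylestradiol minus estradiol. For tetraiodothyroacetic acid minus Tiratricol the count was 55 without tetraiodothyroacetic acid replicate 1, 45 without tetraiodothyroacetic acid replicate 3, 25 without Tiratricol replicate 1, 48 without Tiratricol replicate 2 and 1715 without Tiratricol replicate 3. For triiodothyronine minus Tiratricol the count was 4 without triiodothyronine replicate 3. For triiodothyronine the count was 5 without replicate 4. For dihydrotestosterone the count was 153 without replicate 4. For Abamectin the count was 4 without replicate 1 and 0 without replicate 2. For bisphenol A the count was 268 without replicate 1 and 148 without replicate 2. For bisphenol AF minus bisphenol A the count was 79 without bisphenol A replicate 1, 31 without bisphenol A replicate 2, 302 without bisphenol A replicate 5, 30 without bisphenol AF replicate 2 and 36 without bisphenol AF replicate 4. For bisphenol AF the count was 48 without replicate 2 and 45 without replicate 4. For Butylparaben minus Propylparaben the count was 5 without Butylparaben replicate 3, 6 without Propylparaben replicate 1, 6 without Propylparaben replicate 3 and 8 without Propylparaben replicate 4. For CP-634384 the count was 33 without replicate 3 and 34 without replicate 4. For diisobutyl phthalate the count was 2712 without replicate 2 and 2501 without replicate 3. For Dimethipin the count was 35 without replicate 2 and 33 without replicate 4. For Genistein the count was 449 without replicate 1. For Haloperidol the count was 528 without replicate 1 and 485 without replicate 3. For Kepone the count was 185 without replicate 3 and 653 without replicate 4. For Pentachlorophenol the count was 770 without replicate 1 and 855 without replicate 2. For perfluorooctanesulfonic acid the count was 39 without replicate 1, 11 without replicate 3 and 12 without replicate 5. For raloxifene the count was 15 without replicate 1 or 4. Without replicate 1 it was 49 for Tiratricol and 8 for Ziram.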

Other observations

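The comparison of CP-634384 with Tiratricol across the Tiratricol genes was set before its result was seen, and the count of genes called alike was chosen after it.

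Several genes changed with many chemicals. Of the 25 chemicals, fkbp5 was called lower with 10 and higher with 0, cyp1a higher with 6, matn1 and uox lower with 10, ponzr3, klf3, dhrs13a.2 and tefb lower with 9, and opn1lw2 lower with 7 and higher with 3. The gene isg15 was called higher with 5, and cdkn1a with 3, all of them in batch 2. Some further lists gave the following calls with the preset correlation. The pregnane X receptor list was called down in 3 chemicals, the metal list up in 1 and down in 5, the fatty acid oxidation list down in 2 and the hypoxia list down in 2. The muscle list was called up in 1 and down in 3, the heart list up in 1, the erythroid list up in 1 and down in 2, the pancreas and skin lists down in 1 each, the blood vessel list up in 2 and the steroidogenesis list in 0. With the estimated correlation each of these lists, from the pregnane X receptor to the steroidogenesis one, gave 0 calls.

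CP-634384 may act on the genes that the thyroid receptor ligands change. CP-634384 and Tiratricol, which share no DMSO arrays, had 27 features called in the same direction, against 0.02 rises and 0.02 falls for independent lists, which argues against shared controls. Across the 76 features called for Tiratricol, which are not independent replicates, the fold changes of CP-634384 had r = 0.818 with those of Tiratricol. Triiodothyronine had r = 0.85, and the highest of the 14 other chemicals outside batch 1 was -0.124. Of the features called alike in Tiratricol, tetraiodothyroacetic acid and CP-634384 there were 22, with 14 higher and 8 lower, and 9 of them were also called in triiodothyronine. This is a hypothesis from the same arrays, and no binding or reporter data are in the files.

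Other splits of the same arrays into groups of the same sizes were fitted for each comparison with at least 3 arrays per group. In 1 of 35 splits, the real one, the count was as high for these chemicals, given with the real count and the highest of the others: methyltestosterone 2140 and 1045, ethinylestradiol 394 and 204, tetraiodothyroacetic acid 48 and 20, dihydrotestosterone 260 and 75, bisphenol A 409 and 253, bisphenol AF 86 and 2, Butylparaben 430 and 74, diisobutyl phthalate 4187 and 2039. The same held for Dimethipin 55 and 2, Endrin 52 and 0, Genistein 1187 and 552, Pentachlorophenol 1287 and 406, perfluorooctanesulfonic acid 64 and 6, Propiconazole 106 and 38, Propylparaben 667 and 145, Tiratricol 76 and 45, Vinclozolin 39 and 1, Ziram 13 and 6, and Butylparaben minus Propylparaben 15 and 3. For these the share was under 0.05, and 1 of 35 is the smallest share that 35 splits can give. It was not corrected over the comparisons, and arrays on the same slide are not independent. By itself it therefore does not exclude chance. The share was also under 0.05 for the DMSO batches (1 of 100 splits, 826 and 23). Ethinylestradiol minus estradiol gave 4 of 100 (109 and 3091). Methyltestosterone minus dihydrotestosterone gave 3 of 100 (869 and 1507). The same limits apply, so chance is not excluded by this for these either. For ethinylestradiol minus estradiol the other splits as high called 455, 1632 and 3091. That with 455 kept ethinylestradiol against its DMSO arrays, the real contrast. The others point to a further structure. The split with 1507 kept arrays of 1 batch and slide together, so it follows the slide.

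Chance cannot be excluded for estradiol (2 of 35 splits, 226 and 669), raloxifene (7 of 35, 76 and 3123), tetraiodothyroacetic acid minus Tiratricol (2 of 35, 240 and 1923) and bisphenol AF minus bisphenol A (5 of 100, 120 and 4117). Splits with several times the real count point to a structure of the samples. The split with 669 set estradiol replicates 1, 3 and 4, on slides 2 and 3, against replicate 2 and the DMSO arrays. It thus still held most of the exposure. The split with 1923 put both arrays of slide 9 with both arrays of slide 15, so it follows the slide. For raloxifene 5 of the 6 other splits as high separated replicate 5 from replicates 1 and 4. The other split with 120 kept all bisphenol A arrays against their DMSO arrays, so it held that exposure. For Abamectin (2 and 0), CP-634384 (52 and 1), Haloperidol (793 and 0) and Kepone (984 and 0) the 10 splits, of which 1 was as high, are too few for a share under 0.05. No splits were fitted for triiodothyronine, which has 2 arrays.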
